A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

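RNA was sequenced from 2 kinds of budding yeast culture, with 12 libraries each. The hybrid was a diploid cross of the laboratory strain BY4741 and the vineyard-derived strain RM11-1alpha. The co-culture held haploid BY4741 and RM11-1a cells, both of mating type a, grown together. Per the labels, each group had 4 technical-replicate cultures, grown at 30 °C and 250 rpm from an optical density of 0.1 to 1, and RNA was extracted with hot acid phenol, selected on oligo-dT beads and reverse transcribed from oligo-dT. The labels did not tie the 12 libraries of a group to its 4 cultures.

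The deposited files give, for each library and each of 4442 orthologous gene pairs, the raw count of reads over sites that differ between BY and RM, separately for each strain's allele. Per the file headers these are counts with no normalisation, and the values were whole numbers with totals that differed between libraries. The aligner, genome build and read filters are not given in the sources used here, so no coordinates are given. Of the gene pairs, 4325 matched a locus tag of the S. cerevisiae R64 assembly, which supplied gene names, neighbours and coding sequences, and 117 did not match.

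The rule for the units of analysis was set before the data were examined, and the units follow from the counts. Within a group, libraries whose counts differed by no more than sampling noise (chi-square over gene pairs with at least 20 reads in the pair of libraries, p of at least 0.05), while other pairs of that group differed (p under 0.001), were summed by complete linkage. This gave 6 summed libraries per group, called summed replicates 1 to 6. They outnumber the 4 cultures of a group, so at least some share a culture and n = 6 does not count independent cultures. In the hybrid they were library 1, library 2, libraries 3 and 5, libraries 4, 6, 7 and 8, library 9, and libraries 10, 11 and 12. In the co-culture they were library 1, libraries 2, 3 and 4, libraries 5 and 6, libraries 7 and 8, libraries 9 and 12, and libraries 10 and 11.

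Total expression was the sum of both alleles' reads. It was compared between hybrid and co-culture with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after TMM scaling, for genes with a mean of at least 10 reads per library in at least 1 group. Allelic differences came from 1 joint edgeR fit over all allele columns, with the summed library as a block and TMM scaling of each allele column, for gene pairs with at least 100 reads over both alleles in each group. Its RM-minus-BY coefficient in the hybrid is called cis, that in the co-culture is called parental, and their difference, co-culture minus hybrid, is called trans. The scaling sets the typical gene pair to a ratio of 1, which removes unequal strain shares in the flask. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. They measure only the spread between libraries, which may be technical. The common dispersion was 0.00165 for total counts and 9.77e-05 for allele columns. Levels are TMM-normalised read counts scaled to a common library size (CPM) with the SD over 6 summed libraries, and log2 folds carry the model's SE.

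Gene pairs were put in classes from the 3 allelic tests. Cis only means that cis and parental passed and trans did not, trans only means that parental and trans passed and cis did not, and compensatory means that cis and trans passed and parental did not. Where all 3 passed, the class was split by whether cis and trans had the same sign. Any other pattern with a passing test was called ambiguous. For the correlation of cis with trans across gene pairs, the 2 effects used different hybrid libraries, so that they share no counting error. Shares of reads carry exact Clopper-Pearson 95% intervals, which cover counting error only. A count of 0 was given a floor of 3 reads over the group, and ratios on 1 to 3 reads carry exact counting intervals.

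Gene lists, 29 in number, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Lists with fewer than 3 tested members were not tested. Named genes followed a rule fixed before the data were examined. For each comparison it took the 6 largest called changes in each direction, among those with a mean of at least 10 reads per library, counted per allele column in the allelic tests, that either went the same way in every summed library or, for total expression, had groups that did not overlap. It added the 3 members with the smallest p from each list that passed camera. It also added every tested member of the a-specific, haploid-specific and strain marker lists for total expression, and of the strain marker and polymorphic regulator lists for the allelic tests. Genes outside this rule are said to be so. A result that this rule names is not reported here.

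The procedure was tested on simulated data with the depth of these libraries, with 50 changed genes per fold. In the total comparison a 1.25-fold change was recovered in 54% of genes, a 1.5-fold change in 98%, and 2-fold and 3-fold changes in 100%. For cis the same folds were recovered in 40%, 64%, 100% and 100%, for parental in 40%, 74%, 96% and 100%, and for trans in 22%, 52%, 82% and 96%. Unchanged genes made up 6 of 182 total calls, 4 of 156 cis calls, 8 of 163 parental calls and 7 of 133 trans calls. When only cis effects were simulated, 0 of 2661 gene pairs were called in trans. The simulated allelic ratios varied by counting error only, with no further spread between libraries. The rates for cis, parental and trans hold for that case.

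The alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, scaling by library totals without TMM, 1 library size for both alleles, no filter and a filter 10 times as strict, a test against a 1.5-fold change (glmTreat), and the 12 libraries of a group unsummed. They also held a replicate-number block, each group fitted alone, exact tests on pooled reads, leaving out the 20 gene pairs with most reads, and leaving out each summed library. Chosen after seeing the data were the removal of a smooth trend on the A share or the GC share of the coding sequence, equal weights for both strains, leaving out hybrid libraries 1 and 9, leaving out the strain marker genes from the cis and trans correlation, and limma on allele log ratios without pairing. Splits of the summed libraries into other groups, or with alleles swapped, were run for each count of calls. LEU2, URA3, HIS3 and HO were not analysed here.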

Results

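Messenger RNA was measured in a diploid hybrid of the yeast strains BY and RM and in a co-culture of haploid cells of both strains, with reads assigned to the BY or RM allele of 4442 gene pairs. The hybrid libraries held 165503 to 232428 assigned reads each (n = 12, 2556935 in all) and the co-culture libraries 199838 to 227175 (n = 12, 2576715 in all). The median gene pair had 182 reads over the 12 hybrid libraries and 169 over the 12 co-culture libraries. In a single library 260 to 337 gene pairs of the hybrid and 260 to 315 of the co-culture had no read, and 33 and 21 gene pairs had none in any library of the group. The 20 gene pairs with most reads took 14.26 to 15.37% of a hybrid library and 15.54 to 16.05% of a co-culture library. Counts of libraries within a group differed by a median chi-square per degree of freedom of 1.078 in the hybrid (0.99 to 1.716 over 66 pairs) and 1.057 in the co-culture (0.958 to 1.169). Of the 66 pairs, 38 in the hybrid and 16 in the co-culture differed with a chi-square p under 0.001, and the hybrid libraries 1 and 9 differed most (1.716).

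BY alleles supplied 50.32% ± 0.05 of the reads in the hybrid (SD, n = 6) and 45.18% ± 0.10 in the co-culture (SD, n = 6). The difference of 5.14 percentage points was larger than the spread within either group (2-sided exact permutation test, p = 0.00216, the smallest that the 924 splits can give). The 6 summed libraries of a group outnumber its 4 cultures, so they are not all independent, and this p covers the spread between summed libraries only. In the hybrid each cell carries both alleles, whereas the co-culture share also depends on how many cells of each strain the flask held.

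The first comparison asked which genes, summed over both alleles, differed between the diploid hybrid and the haploid co-culture. Genes that haploid cells of mating type a use to mate had far fewer reads in the hybrid. STE2, the receptor for the alpha pheromone, stood at 53.7 ± 9.43 CPM in the hybrid and 7300 ± 249 CPM in the co-culture (n = 6 each), 137-fold lower. All 4 a-specific genes with enough reads to test fell (4 when adjusted over the list alone, camera adjusted p = 9.08e-14, and adjusted p = 0.0239 with an estimated correlation). STE6, the exporter of the a pheromone, fell by 4.87 on the log2 scale (SE 0.08), and BAR1, the protease that degrades the alpha pheromone, fell by 7.12 (SE 0.14). MFA1, which encodes the a pheromone, had 2 reads in the hybrid and 616 in the co-culture, a scaled ratio of 306 (95% counting interval 84.3 to 2530).

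Haploid-specific genes fell as a group as well, in 8 of 8 tested members, with 11 in the files (8 when adjusted over the list alone, camera adjusted p = 2.88e-13, but adjusted p = 0.0553 with an estimated correlation). GPA1, the G-protein subunit of the pheromone response, changed by -4.65 on the log2 scale (SE 0.18). FAR1, which arrests the cell cycle on pheromone, changed by -3.19 (SE 0.08), and SST2, which damps the pheromone signal, by -2.85 (SE 0.10). RME1, a repressor of meiosis, changed by -4.22 (SE 0.35) and TEC1, a regulator of filamentous growth, by -2.95 (SE 0.18). NEJ1, a factor of DNA end joining, changed by -2.84 (SE 0.16), and AMN1, an antagonist of mitotic exit, by -1.48 (SE 0.08). FUS3, the kinase of the mating pathway, had 1 read in the hybrid and 377 in the co-culture, a scaled ratio of 374 (counting interval 66.7 to 14800). The median A share of the coding sequence was 31.4% in the a-specific genes and 33.7% in the haploid-specific genes, against 32.6% over all tested genes.

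Genes of ribosome assembly were higher in the hybrid. Of 37 tested ribosome biogenesis genes, 29 rose, 0 fell and 8 did not pass (29 rose when adjusted over the list alone, camera adjusted p = 2.06e-09, and adjusted p = 0.0304 with an estimated correlation). CBF5, the pseudouridine synthase of ribosomal RNA, stood at 1930 ± 139 CPM in the hybrid and 614 ± 41.9 CPM in the co-culture (n = 6 each), 3.16-fold higher. The helicase gene DBP3 rose by 1.66 on the log2 scale (SE 0.06) and NOP4, which acts in assembly of the large subunit, by 1.68 (SE 0.07). Of 55 ribosomal protein genes 36 rose, 6 fell and 13 did not pass (37 rose when adjusted over the list alone, camera adjusted p = 7.43e-05, and adjusted p = 0.0111 with an estimated correlation). Among them RPS11B changed by 1.28 (SE 0.12), RPL7B by 0.98 (SE 0.09) and RPS9B by 0.52 (SE 0.04). Most ribosomal protein genes have near-identical copies, so values of single members are uncertain, and RPL7B overlaps another annotated gene. The 6 largest rises under the naming rule were those of NOP16 (log2 3.37, SE 0.19), EBP2 (3.21, SE 0.10), RRP36 (3.12, SE 0.15), BUG1 (2.96, SE 0.15), PXR1 (2.83, SE 0.13) and SAS10 (2.83, SE 0.12). Of these NOP16, EBP2, RRP36, PXR1 and SAS10 encode ribosome assembly factors, and BUG1 encodes a Golgi protein. The median A share was 34.1% in the ribosome biogenesis genes and 30.7% in the ribosomal protein genes. The 6 genes with the largest rises had higher A shares, from 38.19% (SAS10) to 42.79% (BUG1), against a median of 32.6% over all tested genes.

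Genes of leucine synthesis, iron uptake and the general stress response were lower in the hybrid. Of 10 leucine and branched-chain genes 8 fell and 2 did not pass (9 fell when adjusted over the list alone, camera adjusted p = 1.07e-05, but adjusted p = 0.0852 with an estimated correlation). LEU1, the isopropylmalate isomerase, changed by -2.17 on the log2 scale (SE 0.06), OAC1, a mitochondrial carrier of the same pathway, by -1.51 (SE 0.07), and BAT1, a branched-chain aminotransferase, by -1.19 (SE 0.05). All 9 tested of the 14 iron regulon genes in the files fell (9 when adjusted over the list alone, camera adjusted p = 3.35e-09, but adjusted p = 0.0814 with an estimated correlation). FET3, the ferroxidase of iron uptake, changed by -1.62 (SE 0.06), and the siderophore transporter genes SIT1 and ENB1 by -1.55 (SE 0.07) and -1.52 (SE 0.07). Of 12 tested stress genes driven by Msn2 and Msn4, with 22 in the files, 11 fell and 1 did not pass (12 fell when adjusted over the list alone, camera adjusted p = 6.13e-05, but adjusted p = 0.0852 with an estimated correlation). HSP12, a small heat shock protein gene, stood at 10.8 ± 5 CPM in the hybrid and 98 ± 15.8 CPM in the co-culture (n = 6 each). The chaperone gene HSP26 changed by -2.93 (SE 0.22) and the glycogen synthase gene GSY2 by -1.43 (SE 0.13). HSP12 and HSP26 met the read minimum only in the co-culture, with 238 and 219 reads there against 24 and 30 in the hybrid. The median A share was 29.7% in the leucine genes, 28.3% in the iron genes and 31.2% in the stress genes.

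Across all genes the change followed the base composition of the coding sequence. The rank correlation across genes of the log2 fold with the A share was 0.553 (2780 of 2793 tested genes had a sequence, and genes are not independent replicates). Of 4 equal sets of genes ordered by A share, the lowest had a median log2 fold of -0.37, with 69 genes higher and 458 lower, and the highest had 0.34, with 384 higher and 47 lower. The correlation of a summed library's own deviation with A share was 0.23 to 0.511 in the 6 hybrid libraries and -0.484 to -0.348 in the 6 co-culture libraries. The deviation was taken from the mean over both groups, so the opposite signs restate the fold, and only the likeness within each group is further information. With this trend removed, an alternative chosen after seeing the data, the 6 largest rises were smaller and their order changed. NOP16 stood at 2.61, EBP2 at 2.42, SAS10 at 2.34, RRP36 at 2.27, PXR1 at 2.11 and BUG1 at 2.02. LEU1 stood at -2.07, FET3 at -1.29 and STE2 at -6.87. The a-specific, haploid-specific and stress lists then had 4, 8 and 12 members that fell, the ribosome biogenesis and ribosomal protein lists 23 and 45 that rose, and the iron and leucine lists 7 and 4 that fell. All 7 lists then passed also with an estimated correlation, with an adjusted p of 0.0183 for the haploid-specific, 0.0498 for the leucine, 0.0461 for the iron and 0.0461 for the stress list.

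In the whole comparison 1712 of 2793 genes passed the edgeR test, 823 higher and 889 lower in the hybrid, with a median absolute log2 fold of 0.50 among them, and 209 changed more than 2-fold. Every gene named above separated the 6 hybrid from the 6 co-culture summed libraries without overlap. Without TMM scaling the median over all genes was 0.12 instead of 0.01 and the split was 1066 higher and 699 lower, so small changes are relative to that choice. With the A-share trend removed 1473 genes passed, of which 1170 were also called before and 1124 of these had the same direction.

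The other tested lists did not pass, the lowest adjusted p being 0.153. With the A-share trend removed, 4 of them passed with higher levels in the hybrid: Hap1 targets (6 of 10 up, 0 down, camera adjusted p = 1.17e-04, and adjusted p = 0.0239 with an estimated correlation), pyrimidine synthesis (5 up and 2 down of 7, 2.7e-03, and adjusted p = 0.0461 with an estimated correlation), methionine and sulfur (5 up and 1 down of 10, 0.019, but adjusted p = 0.0565 with an estimated correlation) and the respiratory chain (12 up and 2 down of 25, 0.0346, but adjusted p = 0.057 with an estimated correlation). Of the strain marker genes, LYS2 of lysine synthesis changed by -0.85 (SE 0.07) and MET17, the homocysteine synthase, by -0.56 (SE 0.16) with overlapping groups, a call that ended with the A-share trend removed (-0.22). MET17 overlaps another annotated gene, so its value is uncertain. Before that removal, the median of the respiratory chain list was below 0 and the mean above, with 6 members up and 6 down of 25, and its median was above 0 without TMM scaling. For the methionine list the test pointed up while the median and mean were below 0, with 3 up and 5 down of 10. The daughter separation list had a median of 0.04 and a mean of -0.02, with 4 up and 3 down of 11, and the hexose transporter list a median of -0.08 and a mean of 0.05, with 1 up of 3.

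**Figure D1:**
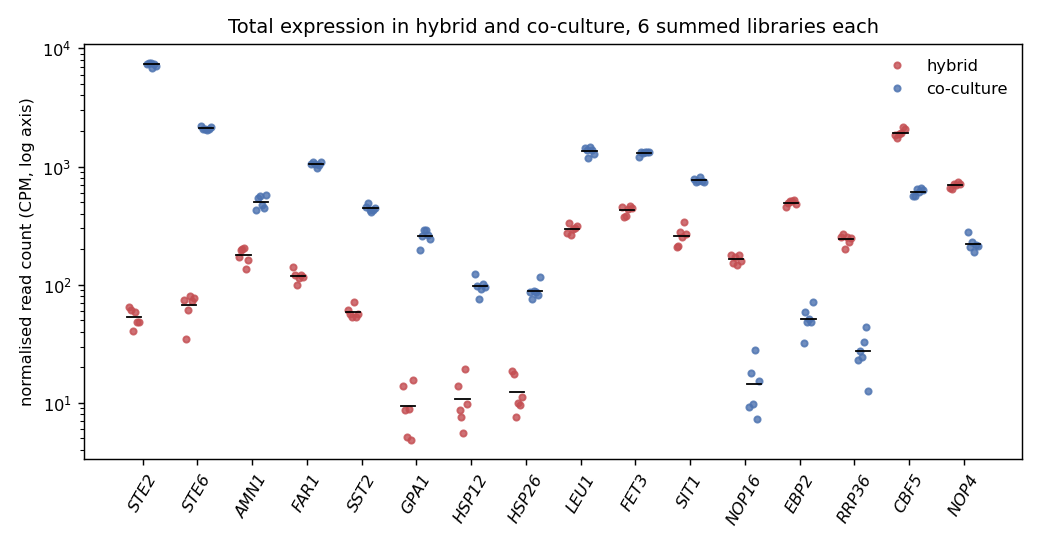
Normalised read count (CPM, log axis) of 16 genes in the 6 hybrid and 6 co-culture summed libraries, with the group mean as a line. STE2 lies at a mean of 53.7 CPM in the hybrid and 7300 CPM in the co-culture, and the points of the groups do not overlap for any gene shown.

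**Figure D2:**
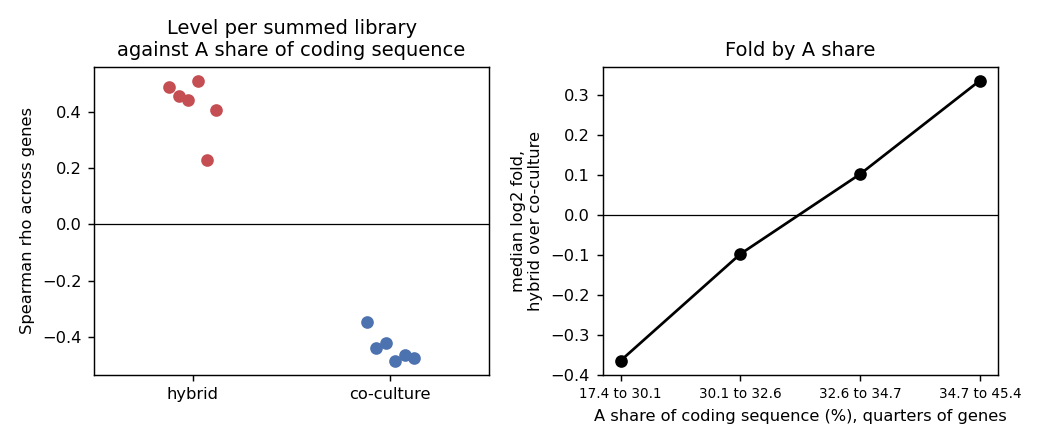
Left, Spearman rho across genes between a summed library's deviation from the mean over both groups and the A share of the coding sequence, with 1 point per summed library. Right, median log2 fold (hybrid over co-culture) in 4 equal sets of genes by A share (percent), which goes from -0.37 in the lowest set to 0.34 in the highest.

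The second comparison asked which alleles differ when both share the hybrid's cells. Such a difference lies on the allele itself or in how its reads were assigned. Read assignment that favours an allele would act alike in hybrid and co-culture, as in the cis only class below. It was not tested across gene pairs. CTR3, a copper transporter gene whose BY-lineage allele is known to carry a transposon insertion, had 6 BY and 194 RM reads, an RM share of 97% (95% interval 93.6 to 98.9). MRH1, which encodes a plasma membrane protein, had a log2 RM-over-BY ratio of -3.31 (SE 0.06), with the RM allele lower in 6 of 6 summed libraries. YIR042C, of unknown function, was higher for RM by 3.17 (SE 0.13), and the phospholipase gene PLB2 by 1.28 (SE 0.06). HAP1, the oxygen-responsive activator disrupted in BY-lineage strains, had a log2 RM-over-BY ratio of -0.97 (SE 0.12), so that its BY allele had more reads. CTR3 is named here by the rule for the parental comparison.

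Among gene pairs with enough reads for the naming rule, the largest RM-higher ratios were, besides YIR042C and PLB2, those of YLR179C (1.88, SE 0.06), YPL088W, a putative aryl alcohol dehydrogenase gene (1.66, SE 0.13), YDR133C, an unnamed reading frame without a match in the annotation used (1.61, SE 0.06), and TAD2, which edits transfer RNA (2.83-fold, log2 SE 0.16). Under the same read minimum the largest BY-higher ratios were, besides LYS2 and MRH1, those of YJR015W (-2.46, SE 0.17), GAS2, a glucanosyltransferase gene (-2.32, SE 0.19), YBR197C (-1.75, SE 0.19) and GPB2, a regulator of protein kinase A signalling (-1.47, SE 0.12). LYS2, a lysine synthesis gene, had 695 BY reads and 2 RM reads in the hybrid, a ratio of 348 (counting interval 95.8 to 2880). In the co-culture it had 586 BY and 590 RM reads, an RM share of 50.2% (47.3 to 53.1), and its small parental ratio (-0.20, adjusted p = 0.0496 in edgeR) was no longer called when any 1 of co-culture summed replicates 1 to 5 was left out (-0.22 to -0.18). MET17, known to be deleted in BY4741, had 0 BY reads in both groups against 149 RM reads in the hybrid and 206 in the co-culture, at least 49.7-fold and at least 68.7-fold higher for RM with a floor of 3 reads over the group.

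Of 2661 gene pairs 534 passed in cis, 275 with RM higher and 259 with BY higher, and 54 of them differed more than 2-fold. Of the 21 lists that could be tested, 0 passed in cis with camera, with the preset or the estimated correlation, and the lowest adjusted p was 0.452, shared by 5 lists. Before adjustment the lowest camera p was that of the Hap1 targets (0.0253), of which 2 were higher and 3 lower for RM of 10 (5 lower when adjusted over the list alone). Among the known polymorphic regulators, 1 was higher and 2 lower of 9. Besides HAP1, CYS4, the cystathionine beta-synthase, stood at -0.19 (SE 0.03) and SIR3, a silencing protein, at 0.28 (SE 0.11), a call that DESeq2 did not make (0.30) and that was lost without hybrid summed replicate 1 (0.27), 2 (0.29), 4 (0.29), 5 (0.25) or 6 (0.27). AMN1, IRA2, MKT1, PHO84, STB5 and ZAP1 did not pass. DESeq2 called 276 gene pairs, all among the 534, and 355 passed without hybrid summed replicate 4, which holds 4 of the 12 libraries.

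The third comparison asked how the strains differ in the co-culture, where each allele works in its own cells. Genes that split daughter from mother cells had fewer RM reads, and genes of respiration and sterol synthesis had more. CTS1, the chitinase that parts the cells, had 2406 BY and 192 RM reads, a log2 ratio of -3.85 (SE 0.08). Of 11 daughter separation genes 9 were lower in RM, 1 was higher and 1 did not pass (9 and 1 when adjusted over the list alone, camera adjusted p = 1.8e-15, and adjusted p = 0.00541 with an estimated correlation). The daughter-specific genes DSE1 and DSE2 stood at -4.70 (SE 0.20) and -4.72 (SE 0.12).

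Respiratory chain genes were higher in RM in 20 of 24 cases, lower in 1 and not passing in 3 (20 and 1 when adjusted over the list alone, camera adjusted p = 7.37e-18, and adjusted p = 0.00827 with an estimated correlation). NDE1, an NADH dehydrogenase of the mitochondrial membrane, stood at 1.70 (SE 0.06), and ATP1 and ATP2, subunits of ATP synthase, at 1.17 (SE 0.06) and 0.95 (SE 0.05). The 1 lower member was COX9, a cytochrome oxidase subunit, at -0.75 (SE 0.27), named after its value was seen. Of 10 Hap1 targets 8 were higher and 2 lower (8 and 2 when adjusted over the list alone, camera adjusted p = 3.9e-08, and adjusted p = 0.00827 with an estimated correlation). CYT1, a cytochrome of complex III, stood at 2.07 (SE 0.13). Of 18 ergosterol genes 14 were higher, 2 lower and 2 not passing (14 and 2 when adjusted over the list alone, camera adjusted p = 1.36e-10, and adjusted p = 0.00102 with an estimated correlation). HMG1, the HMG-CoA reductase of sterol synthesis, stood at 1.83 (SE 0.07), ERG28, a scaffold of the pathway, at 2.41 (SE 0.16). ERG25, a sterol methyl oxidase, stood at 1.12 (SE 0.04), ERG11, the lanosterol demethylase, at 1.03 (SE 0.06), and ERG10, which makes acetoacetyl-CoA, at 0.63 (SE 0.03). The Hap1 and ergosterol lists share members, such as HMG1, and so do the Hap1 and respiratory chain lists.

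Phosphate regulon genes were lower in RM in 5 of 5 tested cases, with 10 in the files (5 when adjusted over the list alone, camera adjusted p = 3.89e-10, and adjusted p = 0.00541 with an estimated correlation). VTC3, which stores polyphosphate in the vacuole, stood at -1.59 (SE 0.04), PHO81, an inhibitor of the kinase of the pathway, at -0.73 (SE 0.07), and the phosphate transporter gene PHO84, which overlaps another annotated gene and is therefore uncertain, at -1.90 (SE 0.05). Iron regulon genes were higher in RM in 7 of 9 cases, lower in 1 and not passing in 1 (7 and 1 when adjusted over the list alone, camera adjusted p = 5.72e-04, and adjusted p = 0.0107 with an estimated correlation). The ferric reductase gene FRE2 stood at 2.67 (SE 0.17), FRE1, of the same family, at 0.68 (SE 0.05), and the iron permease gene FTR1 at 0.74 (SE 0.07). Of 9 methionine and sulfur genes 5 were higher, 1 lower and 3 not passing (5 and 1 when adjusted over the list alone, camera adjusted p = 7.55e-03, but adjusted p = 0.0547 with an estimated correlation). They include MET17, deleted in BY4741, SAM1, an S-adenosylmethionine synthetase gene (0.84, SE 0.03), and MMP1, an S-methylmethionine permease gene (1.12, SE 0.13).

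Of 49 ribosomal protein genes 24 were higher, 7 lower and 18 not passing (25 higher when adjusted over the list alone, camera adjusted p = 1.75e-03, and adjusted p = 0.0116 with an estimated correlation). RPL24B stood at 0.63 (SE 0.05) and RPP0 at 0.59 (SE 0.05). Reads of duplicated members among them may be shared, so single values are uncertain. Of 24 proteasome genes 13 were lower, 1 higher and 10 not passing (13 and 1 when adjusted over the list alone, camera adjusted p = 0.0235, and adjusted p = 0.0429 with an estimated correlation), though their median of -0.20 turned to 0.02 with 1 library size for both alleles, where 3 were higher and 1 lower. The proteasome genes PRE7, RPN1 and RPN3 stood at -0.87 (SE 0.09), -0.25 (SE 0.05) and -0.20 (SE 0.04), and with 1 library size RPN1 was no longer called and RPN3 was at 0.01. Of the 9 known polymorphic regulators 6 were lower in RM and 3 did not pass (6 when adjusted over the list alone, camera adjusted p = 2.7e-05, and adjusted p = 0.014 with an estimated correlation). HAP1 stood at -1.66 (SE 0.11) and AMN1 at -1.15 (SE 0.09). PHO84 of the phosphate list is also among the 6. The smaller ratios of CYS4 (-0.27, SE 0.04), ZAP1, a zinc-responsive activator gene (-0.59, SE 0.20), and MKT1, a regulator of mRNA translation (-0.30, SE 0.11), were not called with 1 library size for both alleles, and MKT1 was also not called without co-culture summed replicate 3 (-0.22) or 5 (-0.20), nor ZAP1 without 6 (-0.46).

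Under the read minimum of the naming rule, large strain differences outside these lists were those of the cell wall gene CWP1 (3.10, SE 0.05), CTR3 (4.78, SE 0.31), YIR042C (3.05, SE 0.15), YPL088W (2.65, SE 0.15), GAS2 (-4.67, SE 0.11), the drug transporter gene QDR2 (-3.20, SE 0.15) and MRH1 (-3.14, SE 0.05). In all, 1072 of 2661 gene pairs passed, 579 higher and 493 lower in RM, and 130 differed more than 2-fold. Because the scaling sets the typical ratio to 1, these are relative values. With 1 library size for both alleles the median over all gene pairs was 0.22 instead of 0.01 and 1248 passed, 1024 higher and 224 lower in RM, whereas without TMM scaling the balance turned, with 475 higher and 601 lower of 1076.

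The fourth comparison asked where the strain difference in the co-culture was not matched by the allelic difference in the hybrid. Such a mismatch can come from effects acting in trans. The groups also differed in ploidy and mating type and had different RM parents. An effect of these on an allele is called trans as well, and the counts cannot tell it apart. Daughter separation and respiration genes had different allelic ratios in the co-culture and in the hybrid, where 2 were higher and 1 lower for RM of 11 daughter separation genes, and 5 higher and 4 lower of 24 respiratory chain genes. DSE1 had a log2 ratio of 0.28 in the hybrid and -4.70 in the co-culture, a difference of -4.98 (SE 0.26), DSE2 a difference of -4.83 (SE 0.16), and CTS1, the chitinase gene, 0.48 in the hybrid and -3.85 in the co-culture, a difference of -4.33 (SE 0.11). CYC1, which encodes cytochrome c, differed by 2.44 (SE 0.18), from -0.20 in the hybrid to 2.24 in the co-culture. OLE1, the fatty acid desaturase gene, had 5374 BY and 2408 RM reads in the hybrid and 2325 BY and 5920 RM reads in the co-culture, a ratio of -1.16 (SE 0.04) against 1.14 (SE 0.03).

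All but 1 of the 11 daughter separation genes passed with a lower ratio in the co-culture (10 lower when adjusted over the list alone, camera adjusted p = 8.67e-18, and adjusted p = 0.0028 with an estimated correlation). Of 24 respiratory chain genes 23 were higher and 1 did not pass (23 when adjusted over the list alone, camera adjusted p = 6.89e-23, and adjusted p = 0.00527 with an estimated correlation). RIP1, the Rieske protein of complex III, differed by 2.12 (SE 0.18), CYT1 by 2.11 (SE 0.17), NDE1 by 1.53 (SE 0.08) and ATP2 by 0.96 (SE 0.07). Of 10 Hap1 targets 8 were higher and 2 did not pass (8 when adjusted over the list alone, camera adjusted p = 1.48e-13, and adjusted p = 0.00432 with an estimated correlation). YHB1, a flavohemoglobin gene among them, stood at 0.65 (SE 0.05). Of 18 ergosterol genes 12 were higher, 1 lower and 5 not passing (12 and 1 when adjusted over the list alone, camera adjusted p = 2.25e-11, and adjusted p = 0.00432 with an estimated correlation). The ratio of HMG1 was 2.83-fold higher in the co-culture (log2 SE 0.09), and the log2 differences were 1.21 (SE 0.06) for ERG25 and 0.74 (SE 0.04) for ERG10.

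All 5 tested phosphate genes were lower (5 when adjusted over the list alone, camera adjusted p = 2e-10, and adjusted p = 0.0028 with an estimated correlation). PHO84 stood at -1.90 (SE 0.07), VTC3 at -1.71 (SE 0.06) and PHO81 at -0.55 (SE 0.10). Of 9 iron genes 6 were higher and 3 did not pass (6 when adjusted over the list alone, camera adjusted p = 2.43e-04, and adjusted p = 0.0251 with an estimated correlation). The heme oxygenase gene HMX1 stood at 3.19 (SE 0.39), FRE2 at 2.42 (SE 0.35) and FRE1 at 0.75 (SE 0.07). Of 49 ribosomal protein genes 19 were higher, 1 lower and 29 not passing (19 and 1 when adjusted over the list alone, camera adjusted p = 2.82e-04, and adjusted p = 0.0118 with an estimated correlation). RPS28B stood at 0.52 (SE 0.04), RPP1A at 0.32 (SE 0.04) and RPS13 at 0.23 (SE 0.02). Of 36 ribosome biogenesis genes 10 were higher and 26 did not pass (10 when adjusted over the list alone, camera adjusted p = 8.9e-03, and adjusted p = 0.0191 with an estimated correlation). Among them NOP1, the fibrillarin gene, stood at 0.71 (SE 0.17), NSR1, encoding a nucleolin-like protein, at 0.47 (SE 0.07), and the RNA helicase gene DBP2 at 0.28 (SE 0.07).

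Known polymorphic regulators were lower in 3 of 9 cases, with 6 not passing (3 when adjusted over the list alone, camera adjusted p = 8.97e-04, and adjusted p = 0.0118 with an estimated correlation). These were PHO84, AMN1 at -0.99 (SE 0.16) and HAP1 at -0.69 (SE 0.17). PHO84 is also in the phosphate list and AMN1 in the haploid-specific list, so these lists are not separate results. The regulator list's median of -0.18 turned to 0.04 with 1 library size for both alleles. Of 24 proteasome genes 6 were lower and 18 did not pass (6 when adjusted over the list alone, camera adjusted p = 0.0261, and adjusted p = 0.043 with an estimated correlation). RPN8, a lid subunit, stood at -0.34 (SE 0.11), RPN1 at -0.24 (SE 0.07) and RPN3 at -0.21 (SE 0.06). DESeq2 called none of these 3. Without hybrid summed replicate 4 neither RPN3 (-0.15) nor RPN8 (-0.23) was called, and without co-culture summed replicate 2 RPN1 was not (-0.19). With 1 library size for both alleles 3 proteasome genes were higher and 0 lower, and RPN3 was at 0.01.

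A further 4 lists passed only with the preset correlation. Of 3 haploid-specific genes 2 were lower (2 when adjusted over the list alone, camera adjusted p = 0.0261, but adjusted p = 0.0939 with an estimated correlation). They were AMN1 and FAR1, and the call of FAR1 (-0.57, SE 0.18) ended without hybrid summed replicate 1 (-0.46) or 4 (-0.53). Of 24 mitochondrial ribosome genes 4 were higher (4 when adjusted over the list alone, camera adjusted p = 0.0379, but adjusted p = 0.179 with an estimated correlation). DESeq2 did not call the named ones, MRPL4 (1.01, SE 0.31), MRPS17 (0.93, SE 0.26) and MRPL20 (0.64, SE 0.20). MRPL20 was also not called without hybrid summed replicate 4 (0.49) or co-culture summed replicate 2 (0.56). Of 6 glycolysis genes 2 were higher and 1 lower (2 and 1 when adjusted over the list alone, camera adjusted p = 0.0379, but adjusted p = 0.108 with an estimated correlation). Their median of 0.08 turned to -0.001 without TMM scaling. The glycolytic enzyme genes PFK1 and PGI1 stood at 0.44 (SE 0.06) and 0.31 (SE 0.02). GPM1, the phosphoglycerate mutase gene, stood at -0.10 (SE 0.03), which turned to 0.11 with 1 library size for both alleles and was not called without hybrid summed replicate 4 (-0.07). Of 10 leucine and branched-chain genes 2 were lower (2 when adjusted over the list alone, camera adjusted p = 0.0494, but adjusted p = 0.126 with an estimated correlation). BAT2, the cytosolic branched-chain aminotransferase, stood at -2.80 (SE 0.17) and ILV3, a dehydratase of the pathway, at -0.45 (SE 0.08). The list's median of -0.08 turned to 0.13 with 1 library size for both alleles.

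Other large differences were those of LYS2, whose reads in both groups are given above, QDR2 (-3.48, SE 0.21) and SCW11, a cell wall glucanase gene (-2.62, SE 0.19). Of 2661 gene pairs 552 passed, 319 higher and 233 lower, and 97 differed more than 2-fold. Without TMM scaling 566 passed, 232 higher and 334 lower, and with 1 library size for both alleles 760 passed, 671 higher and 89 lower, with a median over all gene pairs of 0.22 instead of 0.01. DESeq2 called 302, all among the 552.

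Combining the tests, 212 gene pairs were cis only, among them CTR3, MRH1, YIR042C and GPB2, and 345 were trans only, among them DSE1, DSE2, CYC1, CYT1, RIP1, PHO84 and QDR2. A further 57 had cis and trans effects in the same direction, such as HAP1, CWP1, GAS2 and HMG1, and 70 in opposite directions, such as CTS1, OLE1 and BAT2. Another 58 were compensatory, 547 were ambiguous and 1372 had no call. These classes rest on the main scaling. With 1 library size for both alleles, 1248 gene pairs instead of 1072 passed in parental and 760 instead of 552 in trans. Of 339 gene pairs called in both cis and parental tests, 287 had the same direction, 159 higher and 128 lower in RM where 59.8 and 48 would be shared by chance, and 52 had opposite directions. Depth limited these calls, which rose over 4 equal sets of gene pairs from 11.9% in cis, 25.2% in parental and 8.41% in trans in the set with fewest reads to 36.8%, 64.7% and 43.6% in the set with most.

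**Figure D3:**
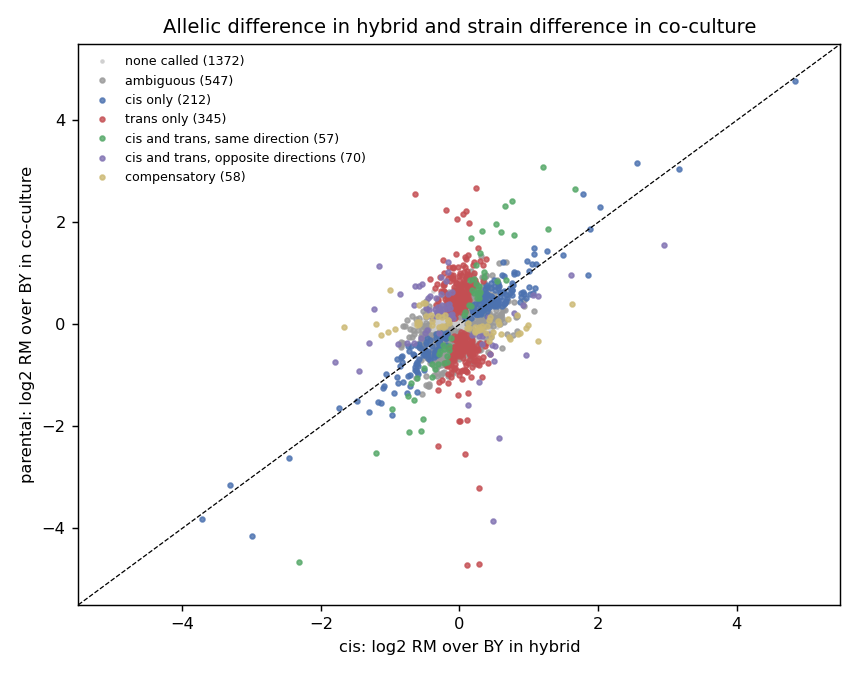
Log2 RM over BY in the hybrid (cis, horizontal axis) and in the co-culture (parental, vertical axis) for each tested gene pair, coloured by class, with a dashed line of equality. The plot leaves out LYS2 and MET17, which lie beyond 5.5, and its legend counts 212 cis only and 345 trans only gene pairs.

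**Figure D4:**
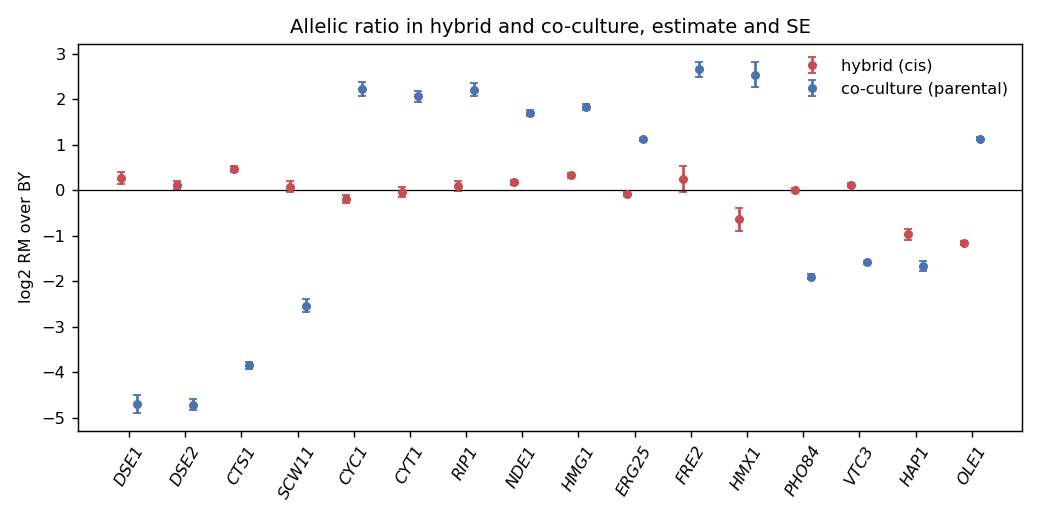
Log2 RM over BY of 16 named genes in the hybrid and in the co-culture, with the model's SE as bars. DSE1 lies at 0.28 in the hybrid and -4.70 in the co-culture, and OLE1 at -1.16 and 1.14.

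Across gene pairs, cis and trans effects estimated from different hybrid libraries were weakly and negatively related, with Pearson's r of -0.124 and Spearman's rho of -0.07 (2661 gene pairs, which are not independent replicates). The strain marker genes LYS2 and MET17 together carried much of Pearson's r. Without them r was -0.055 (bootstrap 95% interval -0.106 to -0.003) and rho stayed at -0.07 (-0.105 to -0.034). From the same hybrid libraries, where both effects share counting error of opposite sign, r was -0.271.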

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

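The tests of base composition, of the cis and trans correlation and of LYS2 were chosen only after the result was seen, whereas the splits of the libraries were set before.

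Single summed libraries lay apart from the other 5 of their group in 13 of 201 sets of values of named genes (6.47%). Chance gives about 1 in 20 if all have equal spread, but the summed libraries held 202848 to 864207 reads. Most of the values below are from co-culture summed replicate 1 and hybrid summed replicates 1 and 2, which hold 1 library each. The iron uptake gene FET3 stood at 1210 CPM in co-culture summed replicate 1, against 1300 to 1340 in the others. The ribosome assembly gene PXR1 stood at 23.1 CPM in the same summed replicate (others 35.7 to 43). The chaperone gene HSP26 stood at 116 CPM in co-culture summed replicate 6 (others 76.3 to 87.7). The mating gene FUS3 stood at 2.55 CPM in hybrid summed replicate 3 (others 0), and MFA1 at 4.67 CPM in hybrid summed replicate 1 (others 0 to 1.11). Over the whole hybrid FUS3 had 1 read and MFA1 2 reads. In log2 RM over BY, hybrid summed replicate 1 stood at 1.92 for FAR1 (others 0.356 to 0.836) and at -0.344 for RPN3 (others -0.0554 to 0.1), and hybrid summed replicate 2 at 1.85 for YIR042C (others 3 to 3.48). Co-culture summed replicate 1 stood at 0.251 for ERG11 (others 0.947 to 1.21), at -5.56 for GAS2 (others -4.58 to -4.39) and at 0.37 for IRA2 (others -0.0196 to 0.119). Co-culture summed replicate 5 stood at 2.66 for CYT1 (others 1.73 to 2.06) and at 2.11 for YIR042C (others 2.93 to 3.36).

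The allelic ratio differed between hybrid and co-culture in 552 gene pairs by the edgeR test of the difference itself. In 52 of them the hybrid and the co-culture ratio were both called with opposite signs. The median co-culture ratio over all gene pairs was 0.01 with the main scaling, 0.22 with 1 library size for both alleles and -0.05 without TMM. Opposite signs of small ratios are therefore relative to that choice. Of the 52, 10 are named genes. Their differences, co-culture minus hybrid, were 2.295 for the desaturase gene OLE1, -4.332 for the chitinase gene CTS1, -2.796 for BAT2, -1.708 for VTC3, 0.74 for ERG10, 0.648 for YHB1, 0.522 for RPS28B, 0.47 for NSR1, 0.307 for PGI1 and 0.228 for RPS13.

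Other splits of the summed libraries gave fewer calls. In the total comparison, 1 of 100 splits, the real one, gave as many as its 1712 calls, and the highest other gave 352. In trans it was 1 of 100, with 552 calls against 131 at most. With alleles swapped within summed libraries, the real arrangement was the 1 of 32 that gave as many calls in cis (534, highest other 232) and in the parental comparison (1072, highest other 480). The real arrangement thus stood apart at the level of summed libraries only, since these outnumber the 4 cultures of each group. The splits run were 100 of 462 possible in the total and trans comparisons, and all 32 in cis and parental. Other arrangements mix real differences into the spread, which lowers their counts (median 0). A difference of preparation or read assignment would also give high counts, so the splits do not tell the source.

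The total log2 fold rose with the A share of the coding sequence across genes (rho 0.553). Stronger amplification of AT-rich cDNA in 1 group predicts the same sign for the T share, but that rho was -0.449 (-0.478 to -0.416). The base shares of a gene sum to a fixed total, so more A tends to leave less T. The rho with GC share was -0.15, the sign that such amplification in the hybrid would give. The T share therefore cannot decide on this explanation. Priming at A runs inside coding sequences predicts an effect of the longest A run at equal A share. That partial rho was -0.053 (-0.092 to -0.014). Without this condition rho was 0.205 for the longest A run and 0.291 for the highest A count in 20 bases. Holding A share equal also removes priming that rises with A share, so this test covers run length alone and cannot decide on priming. The listed ribosome genes were not the whole source, since rho was 0.564 without them. The lists lack some ribosome assembly genes that rose strongly, such as EBP2 and SAS10, with A shares of 41.28% and 38.19%. Such genes stayed in the test, so it cannot decide on ribosome assembly genes as a whole. A recovery of RNA that depends on composition and differed between the preparations of the groups may be at work, and so may a difference of growth or ploidy between hybrid and haploid cells, and neither was tested.

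Cis and trans effects were negatively related across gene pairs. Counting error shared by both effects gives such a relation from the same libraries, where r was -0.271, and simulated data without any effect gave -0.694. The simulated data hold no cis effects, so these r values cannot be compared in size. The covariance was -0.0611 in the data and -0.0259 in the simulated data. Without the strain marker genes it was -0.0377 and -0.0261. With different hybrid libraries and without the strain marker genes r was -0.055. Its bootstrap interval of -0.106 to -0.003 ends close to 0 and takes gene pairs as independent, which they are not. On these values shared counting error was not the whole source, but the rest is small. The cis and the trans estimate may still use libraries of the same culture. Error of a culture or preparation may therefore remain shared, which was not tested. Regulatory changes that offset each other may account for the remainder, as a hypothesis that was not tested further.

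The RM allele of LYS2 had 2 of 697 reads in the hybrid, but an RM share of 50.2% in the co-culture, so its RM reads can be assigned. The 10 nearest measured neighbours had a median RM share of 49.4% in the hybrid (40.1 to 53.2), which argues against the loss of a larger RM segment. The hybrid and the co-culture had different RM parents, RM11-1alpha and RM11-1a. A deletion or disruption of LYS2 itself in the RM parent of the hybrid is a candidate explanation, a hypothesis that read counts per gene cannot test.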

How the results depend on the processing

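Of the alternatives here, the removal of composition trends, equal strain weights, leaving out hybrid libraries 1 and 9, leaving out the strain marker genes and limma without pairing were chosen only after the results were seen. With a filter 10 times as strict, 523 genes and 465 gene pairs were tested, and the counts were 438 for total, 213 for cis, 341 for parental, 250 for trans, 70 for cis only and 115 for trans only, because fewer genes were tested. Against a 1.5-fold change they were 337, 47, 152, 76, 25 and 54, because small folds no longer count. DESeq2 called 276 gene pairs in cis and 302 in trans, and the cause was not tested. Leaving out each summed library gave 1569 to 1715 for total, 355 to 536 for cis, 875 to 1059 for parental, 447 to 531 for trans, 153 to 206 for cis only and 283 to 339 for trans only, with 355 for cis without hybrid summed replicate 4, which holds 4 libraries. The cis and trans correlation was -0.271 from the same hybrid libraries, which share counting error, and -0.055 without the strain marker genes. The difference in BY share was 4.84 points without the 20 gene pairs with most reads. Of the gene lists in total expression 3 passed with an estimated correlation and 11 with the A-share trend removed, and the cause was not tested. With 1 library size for both alleles, which by its construction leaves the strain shares in, the sign changed for CYS4 trans (0.13, not called with the main scaling), GPM1 trans (0.113), LYS2 parental (0.009), RPN3 parental (0.009) and RPN3 trans (0.005). With Fisher's exact test on pooled reads it changed for CYS4 trans (0.131), GPM1 trans (0.112) and RPN3 trans (0.004). That test took raw counts, which leave the strain shares in as well. The median trans value was 0.218 in both settings, so they do not count as separate evidence. Of 1813 alternative values for 151 named results, 1725 kept their side of the threshold with no change of sign in a called value, 75 lost the call, 5 gained it and 8 changed sign while called with at least 1 of the settings. Unsummed libraries gave 1755 for total, 545 for cis, 1078 for parental and 553 for trans, and leaving out hybrid libraries 1 and 9 gave 1692, 447, 1053 and 517. The replicate-number block gave 1777 for total and, by limma on log ratios, 543 for trans against 546 without pairing. Residuals of libraries with the same number correlated at -0.022 to 0.066 (median 0.025, against 0.001 for different numbers), so the numbers showed little pairing. Equal strain weights gave 1556 and removing the GC trend 1701 for total. Depth set the limit for small effects, the median SE of a trans effect going, over 4 equal sets of gene pairs, from 0.334 in the set with fewest reads to 0.107 in the set with most.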

Other observations

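The genes and values in this part were chosen only after they were seen. The 2 tested genes of the pheromone-induced list both fell in the hybrid in edgeR, PRM5 with a log2 change of -2.47 (SE 0.25) and the agglutinin gene AGA1 from 336 ± 28.4 CPM in the co-culture to 80 ± 9.27 CPM in the hybrid (SD, n = 6 each). The list was too short for camera. Of the a-specific, haploid-specific and pheromone-induced genes with too few reads for the total test, all but FIG2 and FUS2 had fewer reads in the hybrid, and none of these was tested. STE18, the gamma subunit of the pheromone G protein, had 1 read in the hybrid and 62 in the co-culture, a scaled ratio of 61.5 (counting interval 10.6 to 2470). KAR4, a regulator of mating genes, had 1 and 76 reads, a ratio of 75.4 (13.1 to 3020), and FUS1, a cell fusion gene, 2 and 20 reads, a ratio of 9.92 (2.41 to 87.6). The haploid-specific gene DCS2 had 12 and 14 reads, and the pheromone-induced genes FIG2, FUS2 and PRM3 had 38 and 29, 3 and 2, and 55 and 71. The a-specific gene ASG7 had 20 and 73 reads and the haploid-specific gene AXL1 10 and 104. PRM1, PRM2, PRM4 and KAR5, all pheromone-induced, had 16 and 32, 72 and 106, 24 and 59, and 55 and 100. The alpha-specific genes had few reads in both groups, 3 and 3 for the a pheromone receptor gene STE3, 28 and 17 for the agglutinin gene SAG1, and 34 and 96 for AFB1, which encodes a blocker of the a pheromone.

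Further genes outside the naming rule had opposite allelic ratios in hybrid and co-culture, both called. RPI1, a regulator of cell wall genes, had a log2 RM-over-BY ratio of 0.96 (SE 0.12) in the hybrid and -0.60 (SE 0.12) in the co-culture. HSL1, a kinase gene of the morphogenesis checkpoint, had -1.23 (SE 0.07) and 0.29 (SE 0.07). The polyamine exporter gene TPO1 had -0.86 (SE 0.16) and 0.59 (SE 0.11), the acetyl-CoA synthetase gene ACS2 -0.16 (SE 0.05) and 1.23 (SE 0.05), and the ADP/ATP carrier gene PET9 -0.16 (SE 0.03) and 1.02 (SE 0.04). SUN4, a cell wall gene of septation, had 0.28 (SE 0.08) and -1.13 (SE 0.06).

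A few alleles had hardly any reads. DNF2, which encodes a phospholipid flippase, had 71 BY reads and 1 RM read in the hybrid and 80 and 0 in the co-culture, where 0 allows an RM share of up to 4.51% (exact interval). IME1, the activator of meiosis, had 44 BY and 3 RM reads in the hybrid and 38 and 0 in the co-culture. Medians of the log2 values per chromosome stayed within -0.18 (chromosome 1) and 0.06 (chromosome 5) for total expression, and within -0.05 (chromosome 9) and 0.06 (chromosome 3) for cis ratios.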
